A study of Mus musculus with 6 samples.

How the data were processed

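RNA was measured by sequencing in mouse bone marrow cells of the BALB/c strain, in 6 libraries from 2 groups of 3. Per the labels, marrow enriched for stem and progenitor cells was infected with retrovirus carrying a hairpin against Cxxc5 (shCxxc5) or a non-targeting hairpin (shCtrl), and GFP-positive LSK cells pooled from several animals were sorted by flow cytometry. Per the labels' protocols, RNA came from 20000 to 50000 sorted cells, and libraries were made with a stranded mRNA kit and sequenced on an Illumina HiSeq instrument. The labels name both a single-read and a paired-end run type without saying which library had which.

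Raw read counts per gene were deposited as a table of 49671 Ensembl gene identifiers. Per the submitters' processing notes, reads were aligned to GRCm38 with STAR 2.5.2b, counted with featureCounts 1.5.1 and analysed with DESeq2. The strand setting of the counting and the annotation release are not given in the sources used here, so reads of overlapping genes on opposite strands could not be told apart. Symbols came from GENCODE M21 (GRCm38): 49326 identifiers matched by identifier, and the other 345, which held 0.0761% of counts, kept their identifiers. For 22654 genes the count was 0 in all 6 libraries. Library totals are given per sample with the results. The counts carry no molecular identifiers. Intervals in the text are over genes and cover no spread between animals.

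Counts were compared with edgeR 4.0.16 in R 4.3.3, with TMM scaling, genes kept by filterByExpr (14637 of them) and the robust quasi-likelihood test on the group alone. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, and log2 fold changes are shCxxc5 over shCtrl. Their standard errors (SE) were derived as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. CPM values are TMM-scaled, and log2 CPM has a prior count of 2. Gene lists, 30 of them, were compared with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists; a list needed 5 tested genes. List medians are of edgeR's fitted log2 fold changes. List means beside left-out libraries are mean differences of log2 CPM, camera's scale, and can differ in size from fitted means (-0.95 against -1.72 for megakaryocyte genes). For Cxxc5 an exact two-sided permutation test was added. The groups, this test, the gene lists and the rule for named genes were set before the data were examined.

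Named genes were Cxxc5, then genes with an adjusted p under 0.05, no overlap between the groups, an average log2 CPM of at least 1 and a symbol that is not a clone or predicted name. The 12 of largest absolute log2 fold change per direction were taken, or, with fewer than 5 passing, the 5 of smallest unadjusted p, reported as not passing. For each list described by its members, the 3 tested members of smallest unadjusted p were added, or 4 where the list passed camera. Some genes that this rule takes are not reported here. Other genes named in the text were chosen after their values were seen, and the text says so.

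Replicate numbers 2, 3 and 4 occur in both groups, but the labels do not say what a number stands for. Deviations from the group means correlated across genes at 0.670, 0.554 and 0.489 between the paired libraries numbered 2, 3 and 4, so by this check the numbers paired the samples. Libraries 3 and 4 of opposite groups correlated nearly as well, at 0.489 and 0.475, so the pairing rests on number 2. After this was seen, the comparison was repeated on replicates 3 and 4 alone (4 libraries, 2 per group, 14193 genes, the same test and the same rule for names). A term for the difference of the shCxxc5 effect between replicate 2 and replicates 3 and 4 was also fitted. That fit has 2 residual degrees of freedom, all from replicates 3 and 4, and assumes that the lone replicate 2 libraries vary alike. Its count is given below only with that limit.

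Alternatives were DESeq2 1.42.0, limma-voom, edgeR without robust fitting, 3 other scalings, no filter and a filter of CPM of at least 1 in at least 3 libraries, the replicate number as a block, leaving out each library, and for lists an estimated correlation, fry and ranks. With an estimated correlation, camera also takes its p-values from the residual degrees of freedom. These were 4 over all 6 libraries without a block, and 2 with the replicate block or in replicates 3 and 4. A call lost there does not by itself show that the members were correlated. The code was tested on simulated counts with 100 genes changed by 2-fold and 100 by 4-fold. With no difference between replicate numbers (3 against 3, 14460 genes), edgeR recovered 99% and 100% of them. With replicate means as in the real libraries (14413 genes), it recovered 43% and 84% without a block and 99% and 100% with the block. In the design of 2 against 2 (14095 genes) it recovered 95% and 100%. All simulated counts took their dispersion from replicates 3 and 4, and a changed gene had the same fold in every pair. Apart from the changed genes, both groups also had the same mean for each replicate number. The values over 6 libraries, with or without the block, are therefore not the power of those fits on the real libraries, where each called 0 genes. Libraries of a group were checked for duplicates by a chi-square per degree of freedom on their counts: 2.33 and 2.28 between replicates 3 and 4 and 88.0 to 153 between replicate 2 and the others, so all differed by more than sampling noise and none was counted as a duplicate. The check finds copied counts only, and it does not tell whether replicates 3 and 4 were separate infections or technical repeats. Figures were drawn with matplotlib 3.10.9.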

Results

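The libraries measured messenger RNA in mouse LSK cells, the Lineage-negative, Sca-1-positive, Kit-positive fraction of bone marrow that holds blood stem cells and early multipotent progenitors. The cells carried a retroviral short hairpin RNA against Cxxc5 (shCxxc5) or a non-targeting hairpin (shCtrl), with 3 libraries per group, numbered 2, 3 and 4 in both. Total counts were 23285446, 22554934 and 15002414 in shCtrl replicates 2, 3 and 4 and 27754019, 22959351 and 16558791 in shCxxc5 replicates 2, 3 and 4. The comparison asks which transcripts of these cells differed with the Cxxc5 hairpin. Each library came from a pool of animals, and the labels do not say that the numbers are separate infections, so p-values measure only the spread between these libraries, which may be technical.

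Cxxc5, which encodes a CXXC-type zinc finger protein that binds unmethylated CpG DNA and restrains Wnt signalling, was lower in every shCxxc5 library than in any shCtrl library. Its level was 66.6 ± 13.5 CPM in shCtrl (SD, n = 3) and 14.0 ± 6.31 CPM in shCxxc5 (SD, n = 3). Within the pairs of equal number it was 12.2-fold, 3.43-fold and 3.23-fold lower in replicates 2, 3 and 4, which left 8.20%, 29.1% and 30.9% of the control level. The gene (ENSMUSG00000046668) lies on chromosome 18 of GRCm38, from 35829397 to 35861688 on the plus strand, and its exons share 49 bases with a gene on the same strand and 11 with an antisense gene. Raw counts were 1945, 1342 and 860 in shCtrl and 194, 391 and 290 in shCxxc5. Over all 6 libraries edgeR's quasi-likelihood test gave a log2 fold change of -2.25 (SE 0.40) with a Benjamini-Hochberg adjusted p of 0.940, which did not pass. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. The call depended on the fit: DESeq2 gave an adjusted p of 6.92e-05, edgeR with the replicate block gave 0.327, and edgeR on replicates 3 and 4 gave 1.45e-16 at a log2 fold change of -1.74 (SE 0.07).

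**Figure D1:**
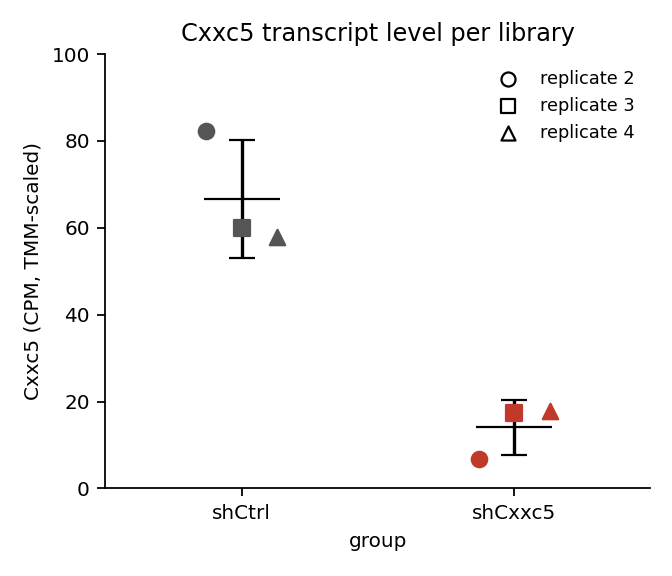
Cxxc5 transcript level in TMM-scaled CPM (y axis) in each library of the shCtrl and shCxxc5 groups (x axis), with marker shapes for replicates 2, 3 and 4, and bars for the mean and SD (n = 3). The shCxxc5 libraries lie at 6.74, 17.4 and 17.9 CPM and the shCtrl libraries at 82.2, 59.9 and 57.9 CPM.

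Over all 6 libraries, the cholesterol synthesis, S phase, G2/M and oxidative phosphorylation lists rose in shCxxc5 cells by camera, and the NF-kB, immediate-early and TGF-beta target lists fell. Each of these calls was lost with the correlation estimated per list, with adjusted p = 0.282 with an estimated correlation for NF-kB and adjusted p = 0.643 with an estimated correlation for the others. The sizes were small. The list of cholesterol synthesis genes had a median log2 fold change of 0.25 over 25 tested genes, with 16 of them higher in all 3 pairs. Among its leading members were Fdps (0.58, SE 0.18), whose exons share 1124 bases with another gene on the same strand, and the cyclase Lss (0.33, SE 0.11). The NF-kB and cytokine list had a median of -0.39 over 29 genes, with 19 lower in all pairs. Nfkbiz, a nuclear regulator of NF-kB targets, stood at -0.78 (SE 0.15), Nfkb2 at -0.49 (SE 0.16), Ptgs2 at -0.54 (SE 0.18) and Tnf at -0.30 (SE 0.10).

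The immediate-early and stress list had a median log2 fold change of -0.38 over 30 genes, with 23 lower in all pairs; Fos stood at -0.50 (SE 0.13) and Jund at -0.41 (SE 0.13). Klf2, a transcription factor that keeps T cells quiescent, stood at -0.91 (SE 0.12), and Junb at -0.45 (SE 0.09). In the TGF-beta and BMP target list (median -0.25 over 23 genes), Skil stood at -0.45, the cell cycle inhibitor Cdkn1a at -0.43 and Smad7 at -0.25. Among 50 S phase genes (median 0.12), 27 were higher in all pairs, with Rrm1 at 0.22, Rrm2 at 0.36 and Cdc6 at 0.34; the flap endonuclease Fen1 stood at 0.46. The G2/M and mitosis list had a median of 0.11 over 54 genes, led by Kif20b (0.24), Mad2l1 (0.18), Nuf2 (0.22) and Cdca3 (0.24); without shCxxc5 replicate 2 the last 2 stood at 0.14 and 0.13. The oxidative phosphorylation list had a median of 0.08 over 75 genes, with 34 higher in all pairs and Sdhd (0.34), Atp5k (0.25), Uqcrh (0.25) and Cox6b1 (0.20) as its leading members; without shCtrl replicate 2 Sdhd stood at 0.23. No gene named in these lists passed edgeR's test over all genes, while Klf2 and Nfkbiz passed in DESeq2. Adjusted over the list alone, 2 members of the immediate-early list (Klf2 and Junb) and 1 of the TGF-beta list (Junb) were lower past the threshold without the replicate block, and 0 members of the other lists in these 2 paragraphs passed. With the block, again adjusted over the list alone, 12 NF-kB, 13 immediate-early and 4 TGF-beta target genes (Skil, Junb, Cdkn1a and Hes1) were lower, and 3 cholesterol synthesis genes (Fdps and Sqle among them), 1 S phase gene (Fen1) and 1 immediate-early gene (Hsp90aa1) were higher. Hes1, Sqle and Hsp90aa1 were named after their values were seen.

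Camera's adjusted p was 2.53e-05 for cholesterol synthesis, 3.32e-05 for NF-kB, 2.82e-05 for S phase, 0.000129 for G2/M, 0.000134 for immediate-early, 0.000198 for oxidative phosphorylation and 0.0400 for TGF-beta genes. With the correlation estimated per list, camera called 0 of 30 lists (adjusted p = 0.282 with an estimated correlation for NF-kB and 0.643 for the others). Among the lists of this paragraph the estimates ran from 0.0094 for NF-kB to 0.55 for S phase genes. For NF-kB, with an estimate near the preset 0.01, camera's unadjusted p still went from 3.32e-06 to 0.00941. Fry called 0 lists and camera on ranks 10. The cholesterol, NF-kB and immediate-early lists were the 3 that stayed called without each library in turn. Without shCtrl replicate 2, camera's adjusted p was 0.318 for oxidative phosphorylation, whose mean difference of log2 CPM went from 0.081 to 0.020. It was 0.0644 for S phase (mean 0.12 to 0.056) and 0.0820 for TGF-beta genes (-0.22 to -0.18). Without shCxxc5 replicate 2 it was 0.594 for G2/M genes, whose mean turned from 0.086 to -0.0096, and 0.183 for TGF-beta genes (mean -0.18). A fit that lacks 1 replicate 2 library keeps the other one of its pair, so differences of replicate 2 in both groups enter it. Medians of those differences were -0.25 for S phase, -0.17 for oxidative phosphorylation and 0.19 for G2/M genes. The TGF-beta call was also lost without shCtrl replicate 4 (0.178), where the mean stayed at -0.22.

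The genes nearest to the threshold over all 6 libraries included the phosphatase gene Dusp5, with a log2 fold change of -0.65 (SE 0.08), Klf2, the ubiquitin ligase gene Rnf180 (-0.89, SE 0.13), Mcf2l (-1.09, SE 0.19) and Coq8a (-0.67, SE 0.12) of coenzyme Q synthesis. On the higher side were Shoc2 (0.58, SE 0.10), a scaffold of Ras signalling, Mat2a (0.44, SE 0.08), which makes S-adenosylmethionine, Pip4p2 (0.75, SE 0.14), Fen1 (0.46, SE 0.09) and Ftsj3 (0.37, SE 0.07) of ribosome assembly. None of these passed edgeR's quasi-likelihood test over all 6 libraries (adjusted p of 0.940 for each). DESeq2 over the same libraries gave an adjusted p of 0.000177 for Klf2, 0.000812 for Rnf180, 0.00195 for Dusp5 and 0.00384 for Mcf2l. Shoc2 and Pip4p2 also passed there (0.0497 each), and Coq8a, Mat2a, Fen1 and Ftsj3 did not. In replicates 3 and 4, which are part of these libraries, all of the genes named so far in this paragraph passed edgeR's test. The rule took genes without overlap between the groups, which fixed the same direction in all 3 pairs, so that agreement is no support. Exons of Fen1, Dusp5, Mat2a, Coq8a, Mcf2l and Shoc2 share 2039, 547, 508, 366, 342 and 97 bases with antisense genes, which counting without strand would mix. In all, edgeR called 0 of 14637 genes, with 575 at an unadjusted p under 0.05, against 732 expected by chance. By other fits, limma-voom called 0, edgeR with the replicate block 0 (1796 at an unadjusted p under 0.05), DESeq2 12 (Shoc2 and Pip4p2 higher and 10 lower) and DESeq2 with the block 139 (19 higher and 120 lower). Genes whose groups did not overlap made up 13.1%, against 10% by chance.

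The lineage and HSC lists called over all 6 libraries had larger medians in the replicate 2 pair than in the others. The granulocyte and monocyte progenitor list had median log2 ratios of 1.66, 0.02 and 0.00 in pairs 2, 3 and 4, and the mast cell, basophil and eosinophil list 1.75, -0.10 and -0.24. Myeloperoxidase (Mpo) stood at 1.80 (SE 0.84) over all libraries and at 3.01 in pair 2, proteinase 3 (Prtn3) at 1.19 and 2.62, Ms4a3 at 1.72 and 3.27, and the chaperone gene Calr at 0.56 and 1.15. In the mast cell and basophil list, Mcpt8 stood at 2.15 over all libraries, Ms4a2 at 2.06, Prss34 at 1.75 and Cd200r3 at 1.16. Without shCxxc5 replicate 2, Mpo stood at 0.14, Prtn3 at 0.83, Ms4a3 at 0.44, Calr at 0.33, Mcpt8 at 0.44, Ms4a2 at 0.69, Prss34 at 0.98 and Cd200r3 at 0.31. The megakaryocyte list went the other way, with median ratios of -2.18, -0.44 and -0.44 in the pairs and 17 of 22 genes lower in all of them; Itgb3 stood at -1.62 (SE 0.73), Tubb1 at -3.06, Cd9 at -0.87 and Gp1ba at -2.18, and without shCtrl replicate 2 these 4 stood at -0.34, 0.99, 0.063 and 0.64. The list of HSC and self-renewal genes had medians of -0.53, -0.13 and -0.17, with 18 of 30 lower in all pairs. Egr1, which is also on the immediate-early list, stood at -0.82 (SE 0.29). Mycn stood at -0.42, Prdm16 at -0.57 and Gprasp2 at -0.50, whose exons share 376 bases with another gene on the same strand. Without shCtrl replicate 2, Egr1 stood at -0.45, Mycn at -0.16 and Prdm16 at -0.22, and without shCtrl replicate 4 Gprasp2 stood at -0.30. Fits without 1 replicate 2 library keep the other one of its pair, so differences of replicate 2 in both groups enter these values. In replicates 3 and 4, 6 of 24 granulocyte and monocyte progenitor genes rose, among them Prtn3 by 0.53, Ms4a3 by 0.27, Calr by 0.23 and Mpo by 0.16, and 4 fell (Gstm1, Alas1, Csf3r and Csf1r). In the mast cell, basophil and eosinophil list 3 of 25 rose there, Mcpt8 by 0.61, Ms4a2 by 0.50 and Prss34 by 0.77, and 8 fell (12 adjusted over the list alone). Gstm1, Alas1 and Csf3r were named after their values were seen. Over all 6 libraries without the block, 0 members of these 4 lists passed edgeR's test, over all genes or adjusted over the list alone; with the block 13 megakaryocyte genes were lower adjusted over the list alone, and 0 members of the other 3 lists passed.

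Camera's adjusted p over all 6 libraries was 0.00155 for granulocyte and monocyte progenitor genes, 0.00139 for mast cell, basophil and eosinophil genes, 0.0195 for HSC genes and 0.0290 for megakaryocyte genes, with adjusted p = 0.643, 0.643, 0.643 and 0.749 with an estimated correlation. The estimated correlations were 0.28, 0.48, 0.14 and 0.98 in that order, all above the preset 0.01. Each of these calls was lost without at least 1 library. Without shCtrl replicate 2 the adjusted p was 0.153 for granulocyte and monocyte progenitor genes, whose mean difference of log2 CPM went from 0.50 to 0.40. It was 0.318 for mast cell, basophil and eosinophil genes, whose mean was 0.51 before and 0.50 after. It was 0.675 for HSC genes (mean -0.33 before and -0.030 after) and 0.166 for megakaryocyte genes, whose mean turned from -0.95 to 0.48. That fit has no block and keeps shCxxc5 replicate 2, so differences of replicate 2 in both groups enter it. Megakaryocyte genes were higher in replicate 2 by a median of 3.46. Their median ratios were below 0 in all 3 pairs, so the turn does not show a rise in the other libraries. Without shCxxc5 replicate 2 the adjusted p was 0.594 for the granulocyte list (mean 0.10) and 0.945 for the mast cell list, whose mean turned to -0.091. Without shCxxc5 replicate 4 it was 0.0949 for HSC genes (mean -0.23) and 0.267 for megakaryocyte genes (-0.54). Without shCxxc5 replicate 3 it was 0.229 for megakaryocyte genes (-0.51).

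**Figure D2:**
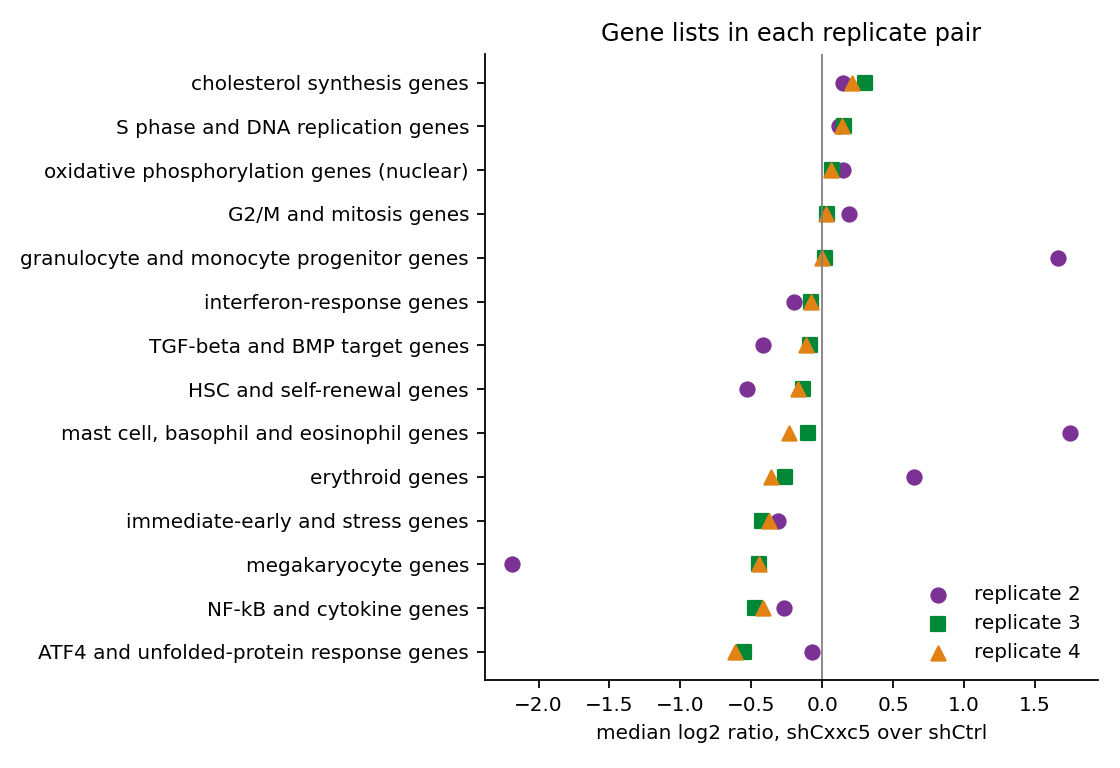
Median log2 ratio of shCxxc5 over shCtrl (x axis) for the 14 gene lists described by their members (y axis), with a marker for each pair of replicates 2, 3 and 4. The megakaryocyte list lies at -2.18, -0.44 and -0.44 and the mast cell, basophil and eosinophil list at 1.75, -0.10 and -0.24, while the NF-kB list lies at -0.27, -0.48 and -0.42.

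The replicate 2 libraries of both groups stood apart from the other 4, and lineage, interferon and sort marker genes moved with them. The interferon-response list was lower in them for 46 of 46 genes (median log2 difference -2.25), with Isg15 at -3.56 and Irf7 at -2.87. Ly6a, which encodes the sort marker Sca-1, lay at 46.4 CPM in shCtrl replicate 2 and 33.1 CPM in shCxxc5 replicate 2, against 804, 786, 703 and 711 CPM in the other libraries; the sort marker gene Kit differed by -0.19 (SE 0.08). Megakaryocyte genes were higher in replicate 2 for 22 of 22 genes (median 3.46), with the platelet genes Pf4 at 5.03 and Vwf at 5.34, and 17 of 19 erythroid genes were higher (median 2.62). These genes were named after their values were seen. Over all genes edgeR with the group in the fit called 2588 higher and 2742 lower in replicate 2 at an adjusted p under 0.05. The first principal component held 67.6% of the variance and parted replicate 2 from the others, and the biological coefficient of variation was 0.312 over all 6 libraries and 0.0294 in replicates 3 and 4.

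**Figure D3:**
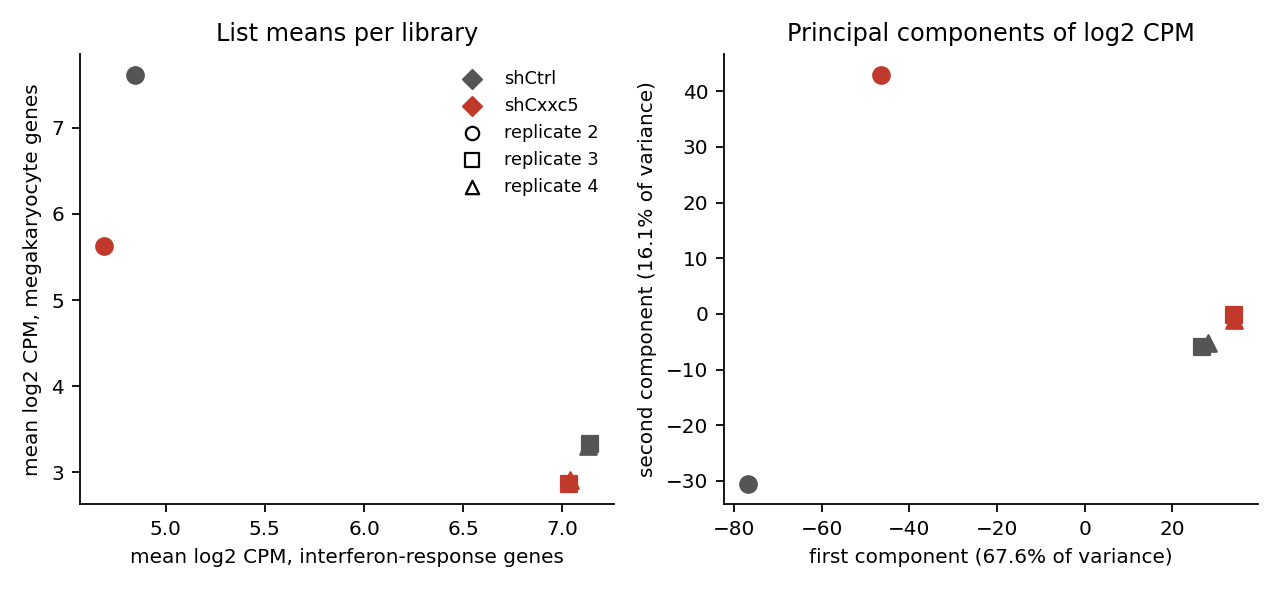
Left, mean log2 CPM of interferon-response genes (x axis) against megakaryocyte genes (y axis) per library, and right, scores on the first (67.6% of variance) and second (16.1%) principal components of log2 CPM, with colors for groups and shapes for replicates. The replicate 2 libraries lie at 4.84 (shCtrl) and 4.69 (shCxxc5) for interferon-response genes, against 7.04 to 7.14 in the others, and at -76.9 and -46.4 on the first component, against 26.8 to 34.2.

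In replicates 3 and 4 alone, a comparison chosen after the structure of the libraries was seen, the ATF4 and unfolded-protein response list fell in shCxxc5 cells by camera, and the cholesterol synthesis and S phase lists rose. Each of these calls was lost with the correlation estimated per list (adjusted p = 0.280 with an estimated correlation for all 3), a test that rests on 2 residual degrees of freedom there. In order of size, the 12 lower genes named by the rule were P2rx3, an ATP-gated channel gene, with a log2 fold change of -2.84 (2 libraries per group), the cationic amino acid transporter gene Slc7a3 (-2.63, SE 0.13), Cth (-2.61, SE 0.27), which makes cysteine, and the cystine transporter gene Slc7a11 (-2.29, SE 0.10). Then came Sorcs1 (-2.11), Aldh1l2 (-2.04) of mitochondrial folate metabolism, Susd2 (-1.93), the stress regulator Nupr1 (-1.85, SE 0.11), Chac1 (-1.84, SE 0.08), whose enzyme degrades glutathione, Slamf9 (-1.84), the stress regulator Trib3 (-1.76, SE 0.07) and the glycine transporter gene Slc6a9 (-1.74, SE 0.11). In the replicate 2 pair Trib3 (-1.15), Slc6a9 (-1.14) and Nupr1 (-1.13) were lower by over 1 log2 unit. Lower there by less were Slc7a11 (-0.60), Chac1 (-0.43), Sorcs1 (-0.24), P2rx3 (-0.20) and Cth (-0.06). Aldh1l2 (0.20), Slc7a3 (0.22), Slamf9 (0.47) and Susd2 (1.28) were higher there. Exons of Slc6a9 and Aldh1l2 share 1986 and 1056 bases with antisense genes. The rises were smaller, with 12 genes between 0.67 for Slc29a2 and 0.84 for Rnf227; among them were the basophil protease Prss34 (0.77) and Pdp2 (0.72), a phosphatase that activates pyruvate dehydrogenase.

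Members of the ATF4 and unfolded-protein response list moved in both directions in replicates 3 and 4. Of 36 tested members, 22 fell and 8 rose past the threshold, over all genes and also adjusted over the list alone. Among those that fell were Ddit3 (-1.43), Asns (-1.38), Ddit4 (-0.64) and Atf4 itself (-0.64). The 8 that rose were Hspa5 (0.31), Hsp90b1 (0.29), Calr (0.23), Creld2 (0.20), Manf (0.19), Sdf2l1 (0.19), Pdia6 (0.15) and Pdia4 (0.13), which encode proteins of the endoplasmic reticulum. Ddit4, Hspa5, Hsp90b1 and Calr came from the rule for names, the others were named after their values were seen, and no test compared the 2 sets by function. Over all 6 libraries with the replicate block, 17 members were lower and 3 (Hspa5, Hsp90b1 and Manf) higher adjusted over the list alone, against 0 and 0 without it. The median of the list was -0.60 in this fit and -0.07, -0.55 and -0.62 in pairs 2, 3 and 4. Camera gave an adjusted p of 4.05e-07 in replicates 3 and 4 (adjusted p = 0.280 with an estimated correlation), 0.0600 over all 6 libraries and 0.00234 with the replicate block (adjusted p = 0.687 with an estimated correlation and the block).

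**Figure D4:**
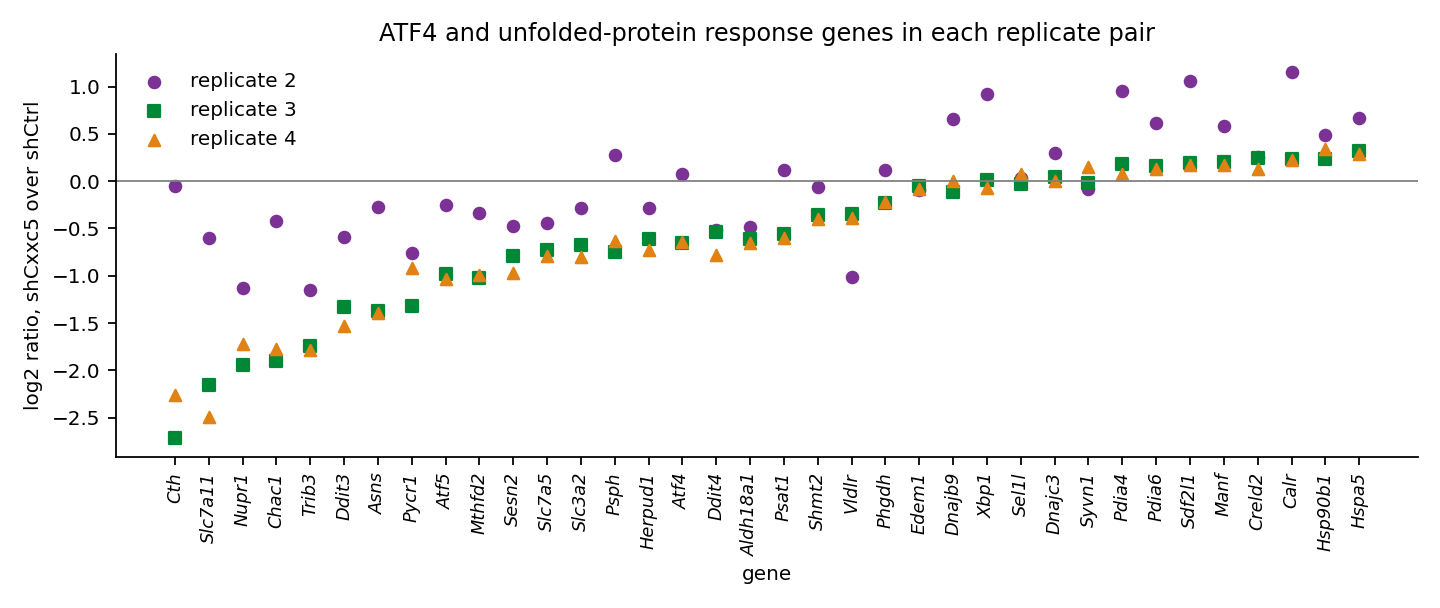
Log2 ratio of shCxxc5 over shCtrl (y axis) for the 36 tested members of the ATF4 and unfolded-protein response list (x axis), with a marker for each pair of replicates 2, 3 and 4. In replicates 3 and 4 the fitted values run from -2.61 for Cth to 0.31 for Hspa5, with 22 of 36 lower and 8 higher past the threshold.

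The cholesterol synthesis, S phase and oxidative phosphorylation lists rose in replicates 3 and 4 by camera, and the NF-kB, immediate-early, interferon-response, megakaryocyte, erythroid and HSC lists fell. Each of these calls was lost with the correlation estimated per list, with adjusted p = 0.548 with an estimated correlation for oxidative phosphorylation, adjusted p = 0.289 with an estimated correlation for erythroid genes and adjusted p = 0.280 with an estimated correlation for the others. In cholesterol synthesis 19 of 25 genes rose (22 adjusted over the list alone) and 0 fell, with Fdps at 0.55 and Lss at 0.42; of 50 S phase genes 29 rose (31 adjusted over the list alone) and 0 fell. In oxidative phosphorylation 15 of 75 rose, also adjusted over the list alone, and 0 fell. In the NF-kB list 17 of 29 fell (20 adjusted over the list alone) and 0 rose, with Nfkbiz at -0.77, Nfkb2 at -0.47, Ptgs2 at -0.60 and Tnf at -0.35. In the immediate-early list 16 of 30 fell (18 adjusted over the list alone), with Fos at -0.63, Klf2 at -0.96 and Junb at -0.39, and 3 heat shock chaperone genes on it rose: Hsp90aa1 (0.26), Hspa8 (0.16) and Dnajb1 (0.13). Of 46 interferon-response genes, 15 fell (17 adjusted over the list alone) and 3 rose (Bst2, Irgm1 and Eif2ak2), with Cxcl10 at -0.91 and Tap1 at -0.20 past the threshold and Nlrc5 at -0.14 not. Megakaryocyte genes fell in 10 of 20 (11 adjusted over the list alone, and 1 higher), Itgb3 among them at -0.69 (SE 0.04). Erythroid genes fell in 8 of 19 and rose in 1 (10 and 1 adjusted over the list alone); the transferrin receptor gene Tfrc rose by 0.28, Nfe2 fell by 0.18, and Car1 stood at -0.48 without passing. HSC genes fell in 9 of 30 and rose in 2, Hlf and Cd34 (12 and 4 adjusted over the list alone), with Egr1 falling by 0.59 and Mycn at -0.08 without passing. The members named here as rising were chosen after their values were seen, except Tfrc and those of the cholesterol list.

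Camera called 10 lists in replicates 3 and 4, with adjusted p of 2.75e-09 for cholesterol synthesis, 4.31e-08 for S phase and for NF-kB, 4.05e-07 for immediate-early, 3.02e-05 for megakaryocyte, 0.000474 for erythroid, 0.00233 for oxidative phosphorylation and 0.00772 for HSC and for interferon-response genes. With an estimated correlation it called 0: adjusted p = 0.548 with an estimated correlation for oxidative phosphorylation, 0.289 for erythroid genes and 0.280 for the others. Among these 10 lists the estimates ran from -0.028 for immediate-early to 0.14 for oxidative phosphorylation genes. For immediate-early genes, with an estimate below the preset 0.01, camera's unadjusted p still went from 6.75e-08 to 0.0256. Fry called 15 lists there, 4 higher and 11 lower, and camera on ranks 10. Oxidative phosphorylation lost its call without shCtrl replicate 3 (adjusted p of 0.0634). The lists of G2/M (0.0848), TGF-beta (0.168), granulocyte and monocyte progenitor (0.798) and mast cell, basophil and eosinophil genes (0.0731) were called over all 6 libraries but not in replicates 3 and 4 by camera, and the mean differences of log2 CPM of the mast cell, basophil and eosinophil list (-0.085) and the granulocyte and monocyte progenitor list (-0.0012) were below 0 there. Erythroid and interferon-response genes were not called by camera over all 6 libraries, with adjusted p of 0.854 at a median of 0.58 and of 0.705 at a median of -0.09.

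Over all genes in replicates 3 and 4, edgeR called 1555 higher and 1278 lower of 14193, and DESeq2 called 728 higher and 502 lower. These calls rest on the spread between replicates 3 and 4 (biological coefficient of variation of 0.0294), which may be technical. The direction split moved with the scaling, from 1555 against 1278 with TMM to 1232 against 1431 with upper-quartile factors and 1120 against 1606 with library totals alone. Without shCtrl replicate 3, shCxxc5 replicate 3 or shCxxc5 replicate 4 the calls numbered 1539, 1507 and 1772. The 12 lower genes named above kept their calls in DESeq2 and without each library, whereas of the 12 higher genes 3 (Rnf227, Prss34 and Pdp2) kept theirs in DESeq2. The other higher genes were Tma7 (0.83), Pxmp2 (0.82), Ifi205 (0.77), Siglec1 (0.74), Lrrn4 (0.72), Shisa8 (0.72), Olfm1 (0.69), Tigd5 (0.69) and Slc29a2, and each of these lost its call in DESeq2 and without shCtrl replicate 3, as did Rnf227 in the latter. Of the 24 genes, 14 had the same direction in the replicate 2 pair; among the higher ones Pxmp2, Ifi205, Siglec1, Lrrn4, Shisa8 and Olfm1 did not. Among 1554 genes called higher that were also measured over all libraries, 68.0% were higher in the replicate 2 pair (exact 95% interval 65.6 to 70.3, with genes not independent), against 46.6% of all genes; among 1274 called lower, 67.8% were lower there (65.2 to 70.4), against 53.4%.

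The remaining lists, of signalling pathways, other cell types, metabolism and library quality, were not called by camera over all 6 libraries. The median log2 fold change was -0.04 for Wnt/beta-catenin target genes (adjusted p of 0.705), -0.05 for Wnt pathway components (0.290) and 0.01 for TET, DNMT and CXXC-domain genes (0.987), whose mean was -0.02. It was -0.24 for retinoic acid target genes (0.0600), with 1 member (Tgm2) lower adjusted over the list alone, and -0.13 for Notch target genes (0.574). Among markers of other cells, it was -0.03 for lymphoid-primed progenitor genes (0.987; mean 0.01), -0.07 for mature neutrophil genes (0.987, tested upward against other genes), -0.20 for monocyte, macrophage and dendritic cell genes (0.0600), 0.26 for the 5 B cell genes (0.231), -0.20 for T and NK cell genes (0.217) and -0.18 for stromal and endothelial genes (0.0703). Camera's adjusted p was 0.231 for p53 target genes (median -0.11), 0.201 for glycolysis genes (-0.09), 0.0818 for the 7 mitochondrially encoded genes (0.02), 0.0673 for cytosolic ribosomal protein genes (0.02) and 0.0693 for replication-dependent histone genes (0.05). Copies of ribosomal protein and histone genes may share reads, which leaves those values uncertain. Apart from the retinoic acid list, 0 members of these lists passed edgeR's test without the block adjusted over the list alone. With the block, 7 p53 target genes, 3 glycolysis genes (Vegfa, Slc2a1 and P4ha1), 2 monocyte list genes (Cd74 and H2-Eb1), 2 Notch target genes (Hes1 and Notch3), 1 mature neutrophil gene (Il1b), 1 B cell gene (Cd72) and Tgm2 were lower, and 4 histone genes (Hist1h1b, Hist1h2an, Hist1h2bj and Hist2h2bb) and the Notch target gene Hes6 higher. Erythroid and interferon-response genes had 1 lower member each with the block (Gata1 and Cxcl10). These members, apart from those named by the rule, were chosen after their values were seen. With the replicate block camera called 19 lists, all 11 above among them, and added the ATF4 list (0.00234), interferon-response (0.00703), histone (0.0111), monocyte (0.0356), retinoic acid (0.0385), T and NK cell (0.0396), ribosomal protein (0.0396) and p53 target genes (0.0418). With the block and an estimated correlation it called 0, with adjusted p = 0.687 with an estimated correlation for the ATF4 and histone lists, 0.619 for retinoic acid genes and 0.589 for the other 5.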

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

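The fits on replicates 3 and 4 and the test of a different response in replicate 2 were chosen only after the libraries had been seen, as were the tests of admixed cells, of the megakaryocyte link, of the progenitor mix and of the tRNA synthetases.

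The difference of the shCxxc5 effect between replicate 2 and replicates 3 and 4 passed edgeR's interaction test, with Benjamini-Hochberg adjustment, for 5235 of 14637 genes, 2453 upward and 2782 downward. For Cxxc5 the difference was -1.87 on the log2 scale. That test sets 1 library per group against the spread between replicates 3 and 4, which is small (biological coefficient of variation of 0.0294, against 0.312 over all 6 libraries). It does not separate a different response from ordinary spread between pools, so it does not show that the response to the hairpin, or the depth of the knockdown, differed between replicates.

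The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. Over all 6 libraries the real split gave 0 genes and the highest other split 0, so 10 of 10 were as large. For lists the real split gave 11 and the highest other 15, and 4 of 10 were as large. Splits that kept the replicate 2 libraries together gave 15, 15, 14 and 8 lists, which points to the structure of the samples. Among the 4 splits that part all 3 pairs, the real one gave 11 lists and the others 5, 5 and 7; with replicate 2 as a block it gave 69 genes and the others 0, 0 and 0. In replicates 3 and 4 the real split gave 2833 genes and 10 lists, and the other 2 splits gave 0 genes each and 0 and 1 lists. These splits, and the 4 that part all 3 pairs, are also too few for a share under 0.05. Every split but the real one mixes the groups on each side. A group difference of any cause then adds to the spread within its sides and can lower its counts.

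Replicate 2 of both groups stood apart, with interferon-response genes and Ly6a low and megakaryocyte and erythroid genes high. Depth is argued against, since after all libraries were thinned to the smallest total the first component still held 69.2% of the variance and parted replicate 2. Sca-1-negative megakaryocytic and erythroid cells mixed into otherwise alike LSK cells would dilute Ly6a no more than Flt3, Cd34, Mpo and Ptprc, but Ly6a fell by at least 3.25 log2 units beyond the largest fall among these. That argues against such mixing as the only difference. It does not tell whether these cells were mixed in, since Ly6a is an interferon-induced gene and interferon-response genes were low there too. Mpo rose in shCxxc5 replicate 2 (a fall of -2.91 log2 units), so it does not measure dilution there. A different sort gate for Sca-1 or a different interferon exposure of the cells, alone or with mixed-in cells, stays open and was not tested. A difference of sequencing run also stays open, since the labels do not assign the single-read and paired-end run types to libraries. The gene with the most counts was Gm26917 in both replicate 2 libraries and Rn7sk in the others. The design names no group that parts replicate 2, so no biological explanation was tested.

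In replicates 3 and 4, 22 of 36 members of the ATF4 list were lower in shCxxc5. The GC content and gene length trend is argued against as the whole cause, since removing it left the list at -0.56. A smaller share of megakaryocytic cells stays open: in replicate 2, where the megakaryocyte list fell most (median -2.18), the ATF4 list had a median of -0.073, but that is 1 pair, its members moved both ways there, ATF4-driven tRNA synthetase genes had a median of -0.31, and the ATF4 list was higher in replicate 2 of both groups (median 0.52), as megakaryocyte genes were. Depth was hardly tested, because the mean totals of the groups differed by 1.05-fold there, and thinning left the list at -0.60. Lower activity of the amino acid response that ATF4 drives may account for the pattern, since ATF4-driven tRNA synthetase genes lay below the others by -0.41. Over the 7 whose values had not been seen the difference was -0.25. These genes were chosen as ATF4 targets, so their fall extends the pattern and does not tell its cause. Whether lower activity, if present, came from Cxxc5 loss, from an off-target effect of the hairpin or from culture conditions that differed between the pools stays open.

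Lineage lists lay further apart between shCxxc5 and shCtrl in the replicate 2 pair, which is 1 library per group. Depth is argued against, since thinning left the granulocyte and monocyte progenitor list at 1.60 in that pair against 1.66 before. The granulocyte and mast cell lists lay at least 3.85 log2 units above the megakaryocyte list in that pair and at most 0.46 above it in the others, so a different mix of progenitor types in the replicate 2 pools may account for it. These lists had been seen to move apart before the test was chosen, and a change of these genes within cells would give the same values. A deeper knockdown in that pair, where 8.20% of Cxxc5 was left in the single library, is a biological explanation that stays open and untested with 1 pair.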

How the results depend on the processing

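The fits on replicates 3 and 4, with replicate 2 as a block, and of DESeq2 and limma-voom with the replicate block were chosen after seeing the data; the other alternatives were planned. The cause of the differences below was not tested. Against 0 genes over all 6 libraries, DESeq2 called 12, edgeR with replicate 2 as a block 69, DESeq2 with the replicate block 139, edgeR on replicates 3 and 4 called 2833 and DESeq2 there 1230; the other 15 alternatives gave 0. Cxxc5 stayed lower in all 20 alternatives (-2.46 to -1.73) and passed in 4, at -2.24 (DESeq2), -2.33 (DESeq2 with the replicate block), -1.74 (replicates 3 and 4) and -1.73 (replicates 3 and 4, DESeq2). Against 11 lists over all 6 libraries, the replicate block and the block for replicate 2 called 19 each, an estimated correlation 0, alone, with the replicate block or on replicates 3 and 4, and fry 0; leaving out a library gave 6 to 17. In replicates 3 and 4, against 2833 genes, DESeq2 called 1230 and leaving out a library gave 1507 to 2043, with the lone library of an arm assumed to vary like the others; against 10 lists an estimated correlation called 0, fry 15 (4 higher and 11 lower) and leaving out a library gave 11 to 16. Directions turned in replicates 3 and 4 for Car1 at -0.48 and, also with an estimated correlation, for the means of the mast cell, basophil and eosinophil list at -0.085 and the granulocyte and monocyte progenitor list at -0.0012. Taken over all 6 libraries, values from replicates 3 and 4 turned for Lrrn4 (-0.023), Shisa8 (-0.0077) and the mean of erythroid genes (0.033). List means here are mean differences of log2 CPM; edgeR's fitted mean for erythroid genes was 0.53. Leaving out a library of all 6 moved Tubb1 from -4.16 to 0.99, Cd9 from -1.18 to 0.063, Gp1ba from -3.61 to 0.64, Car1 from -0.97 to 2.98, Nlrc5 from -0.47 to 0.021, Tap1 from -0.47 to 0.036, the mean of megakaryocyte genes from -1.86 to 0.48 and those of mast cell, basophil and eosinophil genes from -0.091 to 0.85 and of G2/M genes from -0.0096 to 0.14. These fits have no block and break a pair, so differences between replicate numbers enter them. Of 60 named genes 23 moved by over 1.5 times or turned when a library was left out, among them Itgb3 (-1.98 to -0.34), Mpo (0.14 to 2.23), Mcpt8 (0.44 to 2.58), Nuf2 (0.14 to 0.26), Cdca3 (0.13 to 0.31) and Sdhd (0.23 to 0.43). Of 1191 values of 60 named genes over all 6 libraries, 1053 kept direction and side of the threshold, 131 passed it and 7 turned; of 335 values of 24 genes in replicates 3 and 4, 277 kept both, 56 lost the call and 2 turned. For the 11 lists 144 of 209 values kept both, 58 lost the call and 7 turned, and for the 10 lists in replicates 3 and 4 it was 125, 14 and 1 of 140. Genes to which DESeq2 gave no adjusted p, or which a filter removed, have no value there. Depth limits the precision of the lowest genes; Tma7, Ifi205 and Siglec1, with group means under 4 CPM, were among those that lost a call.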

Other observations

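The test of tRNA synthetases was chosen after the result for the ATF4 list was seen, and values of 6 of the 13 genes had been seen too.

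Genes for aminoacyl-tRNA synthetases, the enzymes that load amino acids onto tRNA, moved apart in replicates 3 and 4 by whether ATF4 is known to induce them. Of 13 cytosolic synthetase genes on the ATF4-driven side, 11 fell in shCxxc5 and 0 rose by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with a median log2 fold change of -0.38. Cars, for cysteine, fell by 0.70, Sars, for serine, by 0.54, and Gars, for glycine, by 0.51. Of 24 other synthetase genes, including the mitochondrial ones, 0 fell and 5 rose, with a median of 0.03. In the replicate 2 pair the medians were -0.31 and 0.04.

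A hypothesis is that the amino acid response driven by ATF4 was less active in the shCxxc5 cells of replicates 3 and 4. None of the 13 genes is on the 30 lists set before the data were examined. The difference of medians was -0.41, with a bootstrap 95% interval of -0.53 to -0.23 and a two-sided permutation p of 0.00015 over 100000 resamples of genes, which are not independent. Over the 7 genes whose values had not been seen, 5 fell and the difference was -0.25 (permutation p of 0.00418). These values suggest lower activity of that response, and they do not tell what lowered it.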
